A study of Mus musculus with 22 samples.

How the data were processed

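RNA of mouse CD4 T cells was measured on 22 arrays, 1 per culture sample, which fall into 7 groups by the cytokines added during activation. The array has the layout of a whole-genome mouse expression array with several short probes per probe set, and the RNA was biotin labelled, per the labels. The values deposited by the authors are linear probe set intensities between 7.85 and 29817, made with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, equalises the distribution of probe values between arrays and summarises the probes of a set. Whether all 22 arrays were normalised together is not given in the sources used here. The table holds 45101 probe sets, and log2 of each intensity was taken before any test.

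Of these probe sets, 34958 carry 1 gene symbol in the platform annotation used here, 932 carry several and 9211 are unnamed here. No gene was named from a probe set with several symbols. For 34741 of the named probe sets the gene identifier was found in the reference gene table, and 0 symbols had to be updated. The 64 control probe sets were left out of the tests and were used only to compare RNA quality. Each gene was represented by its probe set with the highest mean over all arrays, which left 18193 genes, of which 9010 had more than 1 probe set. Because RMA equalises distributions, a shift shared by most genes cannot be read from these values, and the summary compresses differences of genes near the background. The values carry no detection calls, so a mean level below the lowest median intensity of an array, 37.9, was taken as possibly at background (near background in the text), and a log2 difference from such a level has no exact size. The number of arrays limits the precision.

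The groups, comparisons, gene lists, main model and most alternatives were fixed from the labels before the data were examined. The array codes in the sample descriptions fall into 2 series, which were taken as the 2 independent experiments named in the series design. The main model was limma (version 3.58.1, R 4.3.3) on all 22 arrays with a term for each group and a term for the experiment, so that all groups shared an estimate of the spread (14 residual degrees of freedom, 6.87 prior degrees of freedom). All tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over the genes, and a gene was called changed at an adjusted p below 0.05. Values after ± are standard deviations (SD) where they follow an intensity and standard errors (SE) where they follow a log2 difference. Intensities are plain means of a group, while log2 differences are adjusted for the experiment. The experiment term is a single shift per gene shared by all groups. Where a gene shifted differently between experiments in different groups, differences that involve a group of a single experiment depend on that term. The comparisons within a single experiment were fitted again on the arrays of that experiment alone.

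For each comparison the named genes were the 10 with the highest and the 10 with the lowest log2 difference among genes that passed the threshold, had 1 symbol and had the same sign in every experiment that held both groups. To these were added genes of helper T cell biology chosen in advance, and members of 29 gene lists covering T helper programmes, signalling targets, cytokines and receptors, metabolism, stress and markers of other cell types. The lists have 400 entries, of which 312 different genes were measured, and 3 names were matched through synonyms. Some list members have no named probe set here. A pair of the lists holds the genes that the study itself assigned to the pathogenic and the non-pathogenic side of its Th17 signature. Those genes were chosen on samples of this kind, these included, so their counts are not independent evidence of a direction. Some of them also belong to other lists, such as Ahr and Maf in the Th17 core list and Tbx21, Stat4 and Ccl5 in the Th1 list. Results of such lists are therefore not fully independent of that choice either.

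Lists were tested with camera, which compares the members of a list with all other genes, at a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry, which asks whether the members move one way on balance and compares them with no other gene. Adjusted p-values for lists are over the lists within a comparison. Alternatives left out or replaced the experiment term, used each experiment alone, blocked on replicate or culture numbers, normalised or centred again, filtered genes below the 30th percentile of mean intensity, changed the probe set of a gene, weighted arrays by quality, restricted the fit to the groups compared, required an absolute log2 difference of 1, or left out single arrays. Simulated arrays with 200 changed genes among the 18193 were used to check the procedure. In the comparison of TGF-β3 with TGF-β1 it recovered 61.2% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 9 false calls. In the comparison of TGF-β1 and IL-6 with and without IL-23 it recovered 58.2% and 100%, with 10 false calls. In the comparison of IL-1β, IL-6 and IL-23 with IL-1β and IL-6 it recovered 43.3% and 100%, with 8 false calls, and in that of IL-1β, IL-6 and IL-23 with TGF-β1 and IL-6 it recovered 82.1% and 100%, with 10 false calls. Each gene had the same spread on every simulated array, so the low-quality array of IL-1β and IL-6 described below was not imitated. The 43.3% and the 8 false calls therefore do not cover it. A raised list was called by all 3 list tests in simulated data and 0 of the 28 other lists was. The noise was drawn independently for each gene, so this could not show false list calls that arise from correlation between genes. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

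The labels name 2 independent experiments and say nothing else about the origin of replicate arrays. The p-values therefore measure only the spread between these samples, part of which may be technical.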

Results

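Naive CD4 T cells, sorted from mice as CD44-low and CD62L-high cells, were activated for 60 h on plates coated with antibodies to CD3 and CD28, and their RNA was measured on 22 arrays. Cells received no cytokine (4 arrays) or a mixture that drives Th17 differentiation, the helper T cell programme named after interleukin 17 (IL-17). The mixtures were IL-1β and IL-6 (2 arrays), the same with IL-23 (4 arrays), TGF-β1 and IL-6 (4 arrays), the same with IL-23 (2 arrays), TGF-β3 and IL-6 (4 arrays), and the same with IL-23 (2 arrays). They are written here as IL-1β/IL-6, IL-1β/IL-6/IL-23 and so on. Experiment 1 held 10 arrays and experiment 2 held 12. All arrays without cytokine and with IL-1β/IL-6 were in experiment 2, both TGF-β groups with IL-23 were in experiment 1, and each of the other 3 groups had 2 arrays in each experiment. Median intensity per array ran from 37.9 to 41.5. Arrays of the same group and experiment differed by an SD of 0.162 to 0.486 in log2 intensity over 15 pairs, none of which was identical.

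Replicate 1 of IL-1β/IL-6 stood apart from the other arrays. Its 75th percentile of intensity was 153, against 189 to 206 on the others, and its correlation with any other array across genes was at most 0.979. Its β-actin signal was 0.853 higher on the log2 scale at the 3′ end than at the 5′ end, against 0.157 to 0.618 elsewhere, a measure of RNA degradation. The labels call all mice female, yet transcripts of the Y chromosome were present on 12 arrays, all 10 of experiment 1 and both of IL-1β/IL-6. On these 12 arrays Eif2s3y, a Y-linked translation factor, measured 1170 to 1364 and Xist, the RNA of the inactive X chromosome, 46.0 to 98.5. On the other 10 arrays Eif2s3y measured 11.7 to 17.6 and Xist 4402 to 6383.

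**Figure D1:**
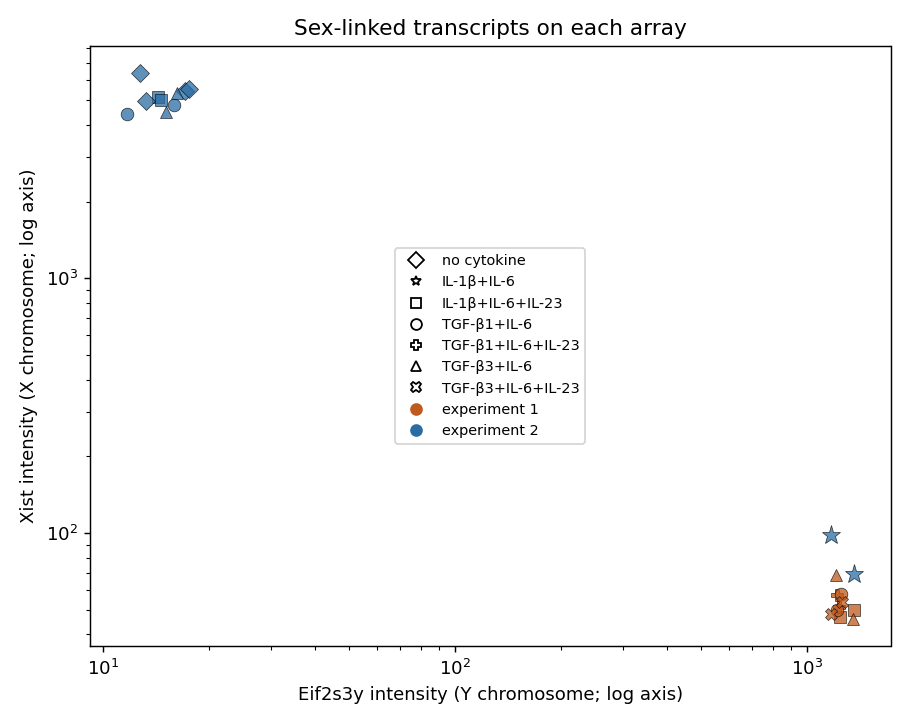
Intensity of Xist (y axis, log scale) against the Y-linked gene Eif2s3y (x axis, log scale), where each point is an array, coloured by experiment. The 12 arrays at the lower right have Xist at or below 98.5 and the other 10 have Xist at or above 4402.

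The first comparisons asked what each mixture changes relative to activation alone. Il17a, the cytokine that defines the programme, measured 55.6 ± 12.8 without cytokine (SD, n = 4), 8912 ± 2430 with TGF-β1/IL-6 (n = 4), 9075 ± 2680 with TGF-β3/IL-6 (n = 4) and 8902 ± 1770 with IL-1β/IL-6/IL-23 (n = 4). With IL-1β/IL-6 it measured 453 ± 35.5 (n = 2). The log2 differences from no cytokine were 6.99 ± 0.13, 7.01 ± 0.13, 7.01 ± 0.13 and 3.05 ± 0.14, with limma adjusted p of 6.7e-20, 6.4e-20, 6.4e-20 and 1.6e-12. Il21, a cytokine that helps B cells and sustains Th17 cells, rose by 6.93 ± 0.22 with TGF-β1/IL-6, 6.44 ± 0.22 with TGF-β3/IL-6, 5.51 ± 0.22 with IL-1β/IL-6/IL-23 and 6.49 ± 0.24 with IL-1β/IL-6. Timp1, an inhibitor of metalloproteinases, rose by 8.61 ± 0.20, 7.83 ± 0.20, 7.49 ± 0.20 and 5.84 ± 0.22 in the same order. Without cytokine Timp1 (30.3) and Il21 (30.8) measured below the median of every array, so the sizes of these differences depend on the background.

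TGF-β1/IL-6 also raised Maf, a transcription factor that drives Il10, by 7.57 ± 0.29, Ahr, the receptor for aryl hydrocarbons, by 3.50 ± 0.15, Il10 itself by 2.90 ± 0.29 and Il9 by 4.63 ± 0.27. It lowered Gzmb, the protease granzyme B, from 6654 ± 242 to 82.9 ± 21.6, a log2 difference of −5.96 ± 0.27. The cytokines Il3 and Csf2, both growth factors of myeloid cells, changed by −5.88 ± 0.32 and −3.80 ± 0.22. Gata3, the regulator of Th2 cells, changed by −3.89 ± 0.26 and its target Il13 by −4.01 ± 0.22. IL-1β/IL-6/IL-23 raised Maf by 2.19 ± 0.29, changed Ahr by −0.72 ± 0.15, Csf2 by −2.31 ± 0.22 and Gzmb by −2.03 ± 0.27, and raised Lum, an extracellular proteoglycan, by 5.07 ± 0.26. Foxp3, the regulator of Treg cells, did not pass in any mixture, with log2 differences of −0.09 ± 0.12 for TGF-β1/IL-6 and −0.26 ± 0.12 for IL-1β/IL-6/IL-23. Maf without cytokine (20.5), and Foxp3 in every group on average, lay below the median of every array, so the sizes of their differences depend on the background. Tbx21, the regulator of Th1 cells, passed only in IL-1β/IL-6, at 2.66 ± 0.63 with an adjusted p of 0.005, on 4 control arrays that spread widely (170 ± 162). Without control replicate 1 or 2 it also passed for IL-1β/IL-6/IL-23, at 1.79 and 1.92, and without control replicate 4 for TGF-β1/IL-6, at −1.51, while against the control arrays with an unexplained g in their titles alone it differed by 0.63 for TGF-β1/IL-6.

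**Figure D2:**
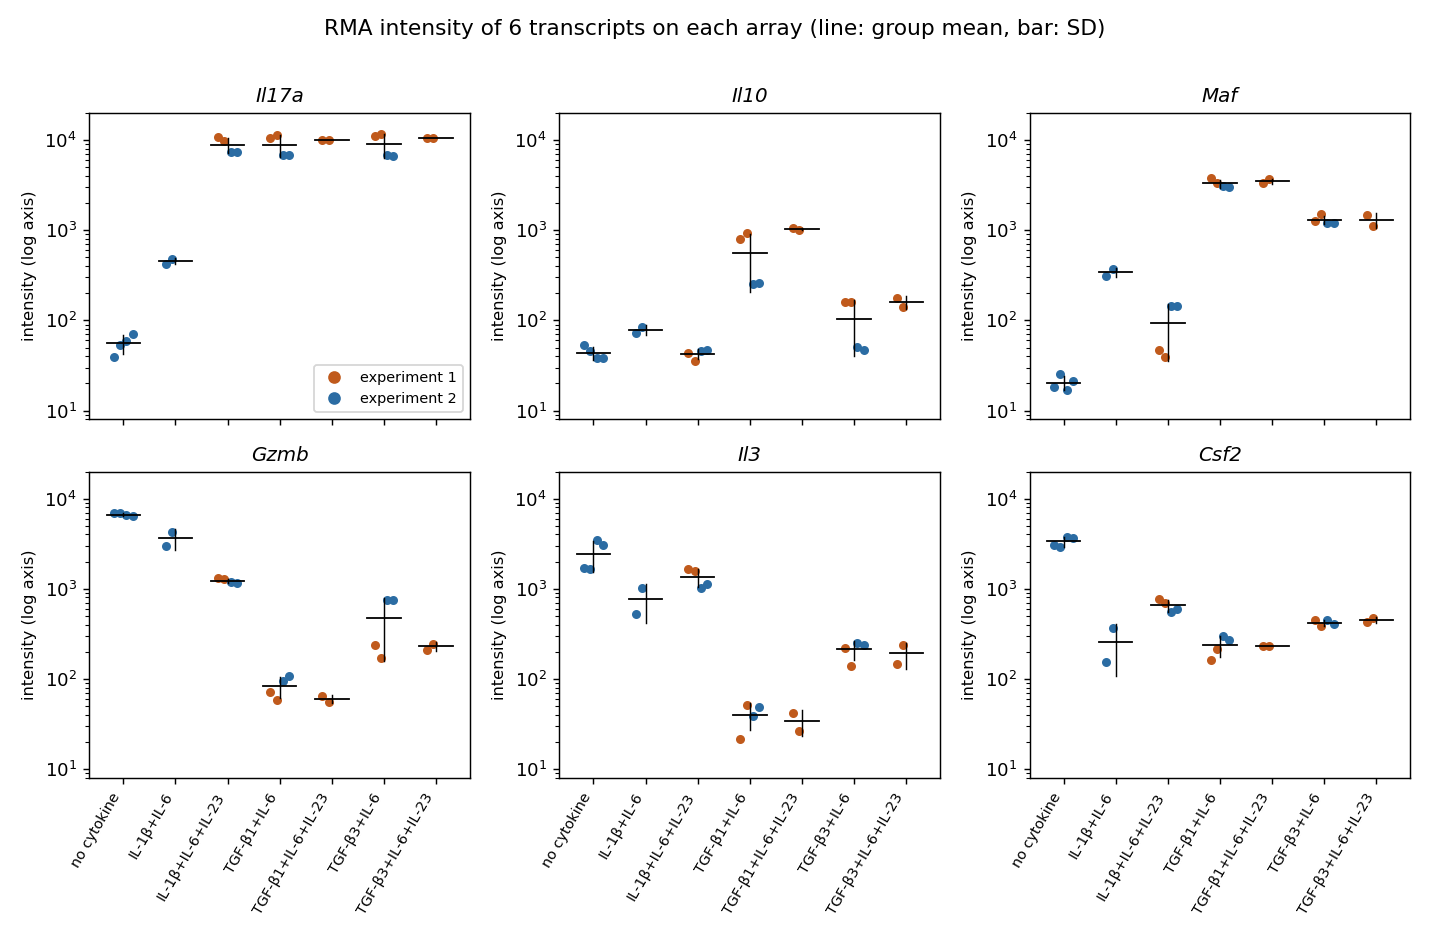
Intensity (log scale) of 6 genes in the 7 groups, where each point is an array coloured by experiment, lines are group means and bars are SD. Il17a lies near 55.6 without cytokine, near 453 with IL-1β/IL-6 and at 8902 or above on average in the other 5 groups, while Il10 averages 557 with TGF-β1/IL-6 and 42.6 with IL-1β/IL-6/IL-23.

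Of 15 measured genes of the Th17 core list, 13 rose and 0 fell with TGF-β1/IL-6 (13 and 0 adjusted over the list alone), among them the chemokine Ccl20 by 2.93 ± 0.34 and the nuclear receptor Rora by 1.99 ± 0.14. With TGF-β3/IL-6, 14 rose and 0 fell (the same adjusted over the list alone), and with IL-1β/IL-6/IL-23, 10 rose and 1 fell (10 and 2). The list was called by camera in all 3, with adjusted p = 6.5e-05, 8.8e-05 and 0.0062 with an estimated correlation. In IL-1β/IL-6, 5 rose and 1 fell (6 and 1 adjusted over the list alone), and the adjusted p of 9.8e-05 became an adjusted p = 0.1 with an estimated correlation. Of 15 genes of the TGF-β response, 11 rose and 1 fell with TGF-β1/IL-6 (13 and 1 adjusted over the list alone, adjusted p = 0.0054 with an estimated correlation), including Pmepa1, a feedback inhibitor of the pathway, by 1.54 ± 0.11 and Skil by 1.05 ± 0.09. With TGF-β3/IL-6, 8 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 0.059 with an estimated correlation). Of 5 targets of the aryl hydrocarbon receptor, 3 rose with TGF-β1/IL-6 (3 adjusted over the list alone, adjusted p = 0.032 with an estimated correlation), namely Cyp1b1 by 1.55 ± 0.28, Ahrr by 1.52 ± 0.12 and Tiparp by 1.47 ± 0.16, where Cyp1b1 and Ahrr were near background without cytokine.

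Genes called changed against no cytokine numbered 3590 with TGF-β1/IL-6 (1991 higher, 1599 lower), 2918 with TGF-β3/IL-6 (1505 and 1413), 2485 with IL-1β/IL-6/IL-23 (1189 and 1296) and 4563 with IL-1β/IL-6 (1386 and 3177). With IL-23 added to the TGF-β mixtures they numbered 2407 for TGF-β1 (1195 and 1212) and 1788 for TGF-β3 (902 and 886). Those groups share no experiment with the control arrays, so these counts rest on the experiment term estimated from groups in both experiments. For IL-1β/IL-6/IL-23 a repeated quantile normalisation gave 1626 higher and 1398 lower genes. Repeating quantile normalisation gave 2248 higher and 2107 lower genes for IL-1β/IL-6, and leaving out its replicate 1 or its replicate 2 gave 1419 or 9012 called genes, and a block on title numbers gave 2381. Leaving out replicate 2 of TGF-β1/IL-6/IL-23 gave 1422, leaving out replicate 1 or 2 of TGF-β3/IL-6/IL-23 gave 981 or 1137, and without the 2 control arrays that have the g the counts were 1905 for TGF-β3/IL-6, 1505 for IL-1β/IL-6/IL-23 and 1944 for IL-1β/IL-6. Leaving replicate 1 of IL-1β/IL-6 out of the shared estimate of the spread gave 3967 for IL-1β/IL-6/IL-23, 3725 for TGF-β1/IL-6/IL-23 and 3160 for TGF-β3/IL-6/IL-23.

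TGF-β3 and TGF-β1 were then compared as partners of IL-6, which asks whether cells with equal Il17a differ by isoform. Il17a differed by 0.02 ± 0.12 on the log2 scale, with an adjusted p of 0.98 (n = 4 each, limma). With TGF-β3, Cxcl3, a chemokine for neutrophils, was higher by 2.60 ± 0.26 (394 ± 49.1 against 71.4 ± 34.5), Il3 by 2.45 ± 0.30, Gzmb by 2.26 ± 0.25 (477 ± 319 against 82.9 ± 21.6) and Csf2 by 0.86 ± 0.20 (421 ± 32.8 against 237 ± 61.8). Il10, an anti-inflammatory cytokine, was lower by a log2 difference of −2.40 ± 0.27 (105 ± 64.5 against 557 ± 352), and so were Il9 by −2.28 ± 0.25, Ahr by −1.56 ± 0.14 and Maf by −1.34 ± 0.27. Nt5e, the ectoenzyme CD73 that makes adenosine, differed by −2.50 ± 0.18. Adjusted p was 9.1e-07 for Cxcl3, 5.1e-06 for Il10, 0.015 for Csf2 and 0.005 for Maf. Csf2 did not pass without replicate 1 or 2 of TGF-β1/IL-6 (0.69 and 0.85) or without replicate 1 or 3 of TGF-β3/IL-6 (0.81 and 0.85).

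Of the 15 measured genes that the study placed on the pathogenic side of its signature, 13 were higher with TGF-β3/IL-6 and 0 lower (14 and 0 adjusted over the list alone), Ccl3 by 1.28 ± 0.25 and Casp1 by 0.80 ± 0.16 among them. All 7 on the non-pathogenic side were lower (7 adjusted over the list alone), Ikzf3 by −1.15 ± 0.14 for example. Adjusted p = 0.0012 and 0.0025 with an estimated correlation, but both lists were chosen on these samples by the study and are not independent evidence. The TGF-β response list, which was not taken from the study, had 6 lower genes and 1 higher of 15 (8 and 1 adjusted over the list alone, adjusted p = 0.0037 with an estimated correlation). Pmepa1 differed by −1.09 ± 0.10, Skil by −0.77 ± 0.08 and Tgfbr1, a receptor for TGF-β, by −0.80 ± 0.12. The Th17 core list had 5 lower genes and 0 higher of 15 (10 and 1 adjusted over the list alone, adjusted p = 0.0029 with an estimated correlation), which were Tmem176a, Tmem176b, Ahr, Maf and Irf4, while Irf4 did not pass without any one of the 8 arrays (−0.28 to −0.32), and Rora at −0.40 ± 0.13 and Il21 at −0.49 ± 0.20 did not pass. Ahr and Maf also belong to the non-pathogenic side of the study, so the result of the Th17 core list is not independent of that choice. In the Treg list 4 of 14 were lower and 0 higher (6 and 2 adjusted over the list alone), with an adjusted p = 0.1 with an estimated correlation. The natural killer cell marker Klrd1 was also lower, by −1.88 ± 0.26.

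In all, 569 genes were called between TGF-β3/IL-6 and TGF-β1/IL-6, 220 higher and 349 lower, of which 78 differed at least 2-fold. A repeated quantile normalisation gave 349 higher and 386 lower. Within experiment 1 the count was 823 (338 higher and 485 lower) and within experiment 2 it was 120 (63 and 57). Leaving out replicate 1 of TGF-β1/IL-6 gave 366 and leaving out replicate 4 of TGF-β3/IL-6 gave 372, while 1110 were called without replicate 1 of IL-1β/IL-6, which enters only the shared spread. The 2 experiments share no array, and 101 genes were called in both, all with the same sign. Of these 48 were higher, where independent lists would share 1.2, and 53 lower, against 1.5. Fisher's exact test on called genes of either sign, which treats genes as independent, gave p = 9.5e-118. Across all genes, which are not independent replicates, the log2 differences of the 2 experiments had a Pearson r of 0.556 and a Spearman rho of 0.298. The median ratio of experiment 2 to experiment 1 was 0.56 over the genes called in experiment 1. Selecting genes by their call in experiment 1 lowers such a ratio by itself, so it does not measure a weaker effect in experiment 2.

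**Figure D3:**
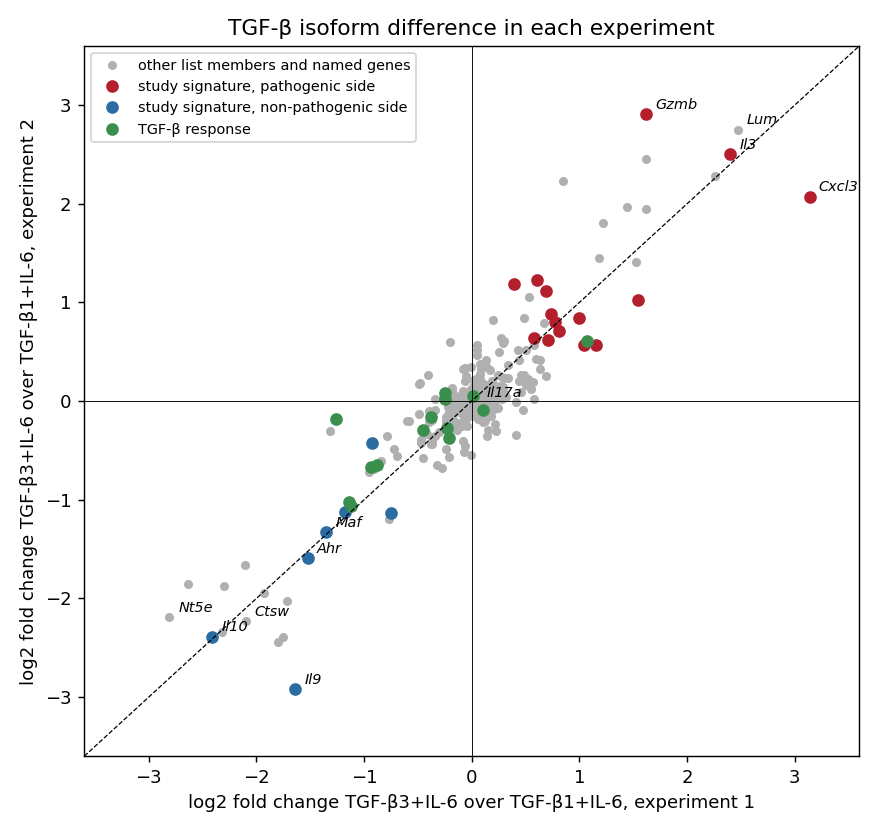
Log2 difference between TGF-β3/IL-6 and TGF-β1/IL-6 in experiment 1 (x axis) and experiment 2 (y axis), where each point is a named gene or list member and colours mark 3 lists. Cxcl3 (3.14 and 2.07) and Nt5e (−2.81 and −2.19) lie on the same side of 0 in both experiments.

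The same isoforms were compared with IL-23 present (n = 2 each, both in experiment 1). Cxcl3 was higher with TGF-β3 by 3.33 ± 0.36, Lum by 2.85 ± 0.34, Il3 by 2.50 ± 0.42 and Gzmb by 1.92 ± 0.36. Nt5e was lower by −2.92 ± 0.25, Il10 by −2.71 ± 0.38 (159 ± 25.3 against 1032 ± 33.2), the cathepsin Ctsw by −2.57 ± 0.20 and Ahr by −1.47 ± 0.20. With TGF-β1/IL-6/IL-23, Cxcl3 (29.5) and Il3 (33.9) were near background. Csf2 at 0.97 ± 0.28 and Maf at −1.44 ± 0.38 did not pass, with adjusted p of 0.15 and 0.091 (limma). On the pathogenic side 5 of 15 genes were higher and 0 lower (13 and 0 adjusted over the list alone, adjusted p = 0.0011 with an estimated correlation), and on the non-pathogenic side 4 of 7 were lower (7 adjusted over the list alone, adjusted p = 0.003 with an estimated correlation), again for lists chosen on these samples. In the TGF-β response list 4 of 15 were lower and 0 higher (6 and 1 adjusted over the list alone, adjusted p = 0.0057 with an estimated correlation). Genes called numbered 187, 77 higher and 110 lower. Of the 120 called without IL-23 in experiment 2, on other arrays, 103 were shared with the 462 called here on experiment 1 alone. All had the same sign, 52 higher where independent lists would share 0.8, and 51 lower against 0.7. Fisher's exact test on called genes of either sign, which treats genes as independent, gave p = 3.9e-150. Leaving out replicate 1 or 2 of TGF-β1/IL-6/IL-23 gave 103 or 64 genes, and leaving out replicate 1 or 2 of TGF-β3/IL-6/IL-23 gave 94 or 65, while 333 were called without replicate 1 of IL-1β/IL-6. Il3 and Gzmb did not pass without replicate 2 of TGF-β1/IL-6/IL-23 (2.17 and 1.81) or without replicate 2 of TGF-β3/IL-6/IL-23 (2.16 and 1.81).

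IL-23, which binds a receptor that Th17 cells acquire, was tested as an addition to each TGF-β mixture. Il17a differed by −0.11 ± 0.15 with TGF-β1 (10020 ± 42.3 with IL-23, n = 2, against 8912 ± 2430, n = 4) and by −0.04 ± 0.15 with TGF-β3 (10630 ± 25.6 against 9075 ± 2680). Csf2 differed by 0.04 ± 0.26 and 0.15 ± 0.26, Il10 by 0.60 ± 0.35 and 0.29 ± 0.35, and Maf by 0.31 ± 0.35 and 0.21 ± 0.35, none of which passed. These differences depend on the experiment term. Within experiment 1, Il10 with IL-23 measured 1055.8 and 1008.8 against 790.4 and 925.6 for TGF-β1, and 176.9 and 141.1 against 159.8 and 161.7 for TGF-β3. Maf measured 3340.5 and 3661.7 against 3773.1 and 3359.6, and 1465.3 and 1127.4 against 1280.8 and 1516.2. By limma 0 of 18193 genes were called in each comparison, while 661 and 380 had an unadjusted p under 0.05, where 910 would be expected by chance. Array quality weights called 4 genes in the TGF-β1 comparison. No member of any of the 29 lists was called, adjusted over all genes or adjusted over the list alone. The B cell markers were called by camera in the TGF-β1 comparison with a median log2 difference of 0.17 and an adjusted p of 0.03, which became an adjusted p = 0.5 with an estimated correlation. The difference between the 2 effects of IL-23 was also tested and 0 genes were called by limma, with 333 at an unadjusted p under 0.05. All arrays with IL-23 in these comparisons came from experiment 1.

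IL-23 was also compared as an addition to IL-1β/IL-6 (n = 4 with and 2 without). Il17a was higher with IL-23 by 3.96 ± 0.15 (8902 ± 1770 against 453 ± 35.5), Ccr6, the receptor for Ccl20, by 2.37 ± 0.23, Cxcl3 by 2.39 ± 0.33, the transcription factor Ebf1 by 2.34 ± 0.22, Lum by 2.18 ± 0.31 and Csf2 by 1.51 ± 0.26 (653 ± 94.6 against 260 ± 152). Lower with IL-23 were the membrane protein gene Gpm6b, by −2.76 ± 0.15, the cytotoxic granule gene Nkg7 by −2.28 ± 0.15, Maf by −1.89 ± 0.35, Gata3 by −1.80 ± 0.32 and Ifng, the Th1 cytokine, by −1.71 ± 0.18. With IL-23 both Ifng (16.6) and Gpm6b (25.3) measured below the median of every array, so the sizes of their differences depend on the background. Adjusted p was 9.3e-14 for Il17a, 0.0019 for Csf2 and 0.0036 for Maf. Within experiment 2, which held both groups, Maf measured 145.9 and 145.1 with IL-23 and 313.4 and 373 without. In experiment 1 it measured 46.8 and 39.7 with IL-23, so the size of the Maf difference depends on the experiment term. Without replicate 1 of IL-1β/IL-6, Csf2 differed by 0.87 and did not pass. Of 14 cytotoxic granule genes 4 were lower and 0 higher (5 and 0 adjusted over the list alone, adjusted p = 0.1 with an estimated correlation). Of 15 genes of cholesterol synthesis 3 were higher, Idi1 by 0.63 ± 0.11 for example, which measured 0.41 and did not pass without replicate 1 of IL-1β/IL-6 (13 adjusted over the list alone, adjusted p = 0.46 with an estimated correlation), and of 22 interferon-stimulated genes 5 were lower (11 adjusted over the list alone, adjusted p = 0.46 with an estimated correlation). In experiment 2 the title numbers 1 and 2 belong only to the IL-1β/IL-6 arrays and to the control arrays without g. Iigp1, a GTPase induced by interferon, measured 603.4 and 697.6 on the former, 491.9 and 508.3 on the latter and 29.6 to 69.4 on the other arrays of experiment 2, so its difference goes with these numbers as well as with IL-23. A block on title numbers can estimate the step between these and the higher numbers only from the control arrays with and without g. It therefore carries the unexplained g difference into this comparison and is no independent test of it. With this block Iigp1 went from −3.50 to 0.02 and Gbp6, another GTPase induced by interferon, from −1.91 to 0.07. Cxcl3 (2.20), Lum (0.80), Csf2 (1.19), Gata3 (−0.46), Maf (−1.70) and Idi1 (0.36) did not pass with it.

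Genes called with IL-23 against without numbered 951, 720 higher and 231 lower, or 607 and 434 after a repeated quantile normalisation. The 2 arrays without IL-23 include the array of lower RNA quality and carry the Y-linked transcripts, and Xist differed by 5.85 ± 0.16 and Eif2s3y by −6.43 ± 0.14. The count was 116 (63 higher and 53 lower) without replicate 1 of IL-1β/IL-6, 8428 without its replicate 2, and 539, 488, 470 or 438 without replicate 1, 2, 3 or 4 of IL-1β/IL-6/IL-23. Within experiment 2 alone it was 71, and with title numbers as a block it was 101 (65 higher and 36 lower). The effect of IL-23 on IL-1β/IL-6 differed from its effect on TGF-β1/IL-6 at 165 genes and from its effect on TGF-β3/IL-6 at 110 by limma interaction tests. Il17a had interactions of 4.07 ± 0.20 and 4.00 ± 0.20, Cxcl3 of 3.42 ± 0.44 and 2.69 ± 0.44, Ccr6 of 2.42 ± 0.30 and 2.32 ± 0.30, and Nkg7 of −2.36 ± 0.21 and −2.18 ± 0.21, where Cxcl3 was near background with TGF-β1/IL-6/IL-23. The most extreme interactions were those of sex-linked genes, Xist at 5.79 ± 0.21 and 5.96 ± 0.21 and Eif2s3y at −6.44 ± 0.18 and −6.30 ± 0.18. The interactions therefore also carry whatever else set the IL-1β/IL-6 arrays apart. Without replicate 1 of IL-1β/IL-6 the interactions numbered 67 and 57, and without its replicate 2 they numbered 7295 and 6596. Against TGF-β1/IL-6 they numbered 60 or 47 without replicate 1 or 2 of TGF-β1/IL-6/IL-23, 93 or 98 without replicate 1 or 2 of IL-1β/IL-6/IL-23 and 81 without replicate 3 of TGF-β1/IL-6. Against TGF-β3/IL-6 they numbered 41 or 43 without replicate 1 or 2 of TGF-β3/IL-6/IL-23, and without its replicate 1 the interaction of Cxcl3 was 2.44 and did not pass.

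IL-1β/IL-6/IL-23 was set against TGF-β1/IL-6 (n = 4 each), which asks how Th17 cells made without added TGF-β differ from those made with it, here with an Il17a difference of 0.02 ± 0.12 on the log2 scale. The mixtures differ in IL-1β, IL-23 and TGF-β1, so no difference between them can be assigned to any one of these cytokines. Higher with IL-1β/IL-6/IL-23 were Lum, by 5.84 ± 0.24 (4328 ± 1400 against 74.7 ± 19.7), Il3 by 5.12 ± 0.30, Serpinb9, an inhibitor of granzyme B, by 4.24 ± 0.14, Gzmb by 3.93 ± 0.25, Il6 by 3.61 ± 0.20, Tbx21 by 2.29 ± 0.52 and Csf2 by 1.49 ± 0.20. Lower were Maf, by −5.38 ± 0.27 (94.4 ± 59.1 against 3309 ± 343), the water channel Aqp3 by −5.32 ± 0.13, Ahr by −4.22 ± 0.14, the membrane glycoprotein Pdpn by −4.15 ± 0.13, Nt5e by −4.12 ± 0.18, Il9 by −3.66 ± 0.25 and Il10 by −3.47 ± 0.27. Adjusted p was 1.7e-13 for Lum, 5.6e-12 for Maf, 0.0035 for Tbx21 and 1.2e-05 for Csf2 (limma). The lower level was near background for Serpinb9, Il6 and Nt5e.

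All 15 genes of the pathogenic side were higher (15 adjusted over the list alone, adjusted p = 0.0021 with an estimated correlation) and 6 of 7 of the non-pathogenic side were lower (6 adjusted over the list alone, adjusted p = 0.0039 with an estimated correlation), in lists the study chose on these samples. Of 15 genes of the TGF-β response, 9 were lower and 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.0065 with an estimated correlation), Pmepa1 by −1.86 ± 0.10 and Tgfbr1 by −1.75 ± 0.12, with Id3 the higher gene at 1.65 ± 0.23. Of the Th17 core list, 9 of 15 were lower and 2 higher (9 and 2 adjusted over the list alone, adjusted p = 0.0025 with an estimated correlation), the higher ones being Batf by 0.99 ± 0.17 and the IL-1 receptor Il1r1 by 0.86 ± 0.11. Of 15 Th1 genes 8 were higher and 2 lower (11 and 2 adjusted over the list alone, adjusted p = 0.059 with an estimated correlation), Cxcr3 by 1.50 ± 0.19 and Stat4 by 1.33 ± 0.16 for example. Ahr and Maf of the Th17 core list and Tbx21, Stat4 and Ccl5 of the Th1 list also belong to the lists the study chose on these samples. Of 14 Treg genes 6 were lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.038 with an estimated correlation). Of 5 targets of the aryl hydrocarbon receptor 2 were lower (3 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation). The 11 co-inhibitory receptors had a median of 0.12 and a mean of −0.34, with 4 higher and 2 lower (4 and 2 adjusted over the list alone), and the tests differed in sign, upward by camera with an adjusted p of 0.33 and downward by fry with an adjusted p of 0.026. Markers of CD8 T cells and natural killer cells were called one by one, Cd8b1 higher by 1.24 ± 0.16 and Klrd1 lower by −2.73 ± 0.26.

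**Figure D4:**
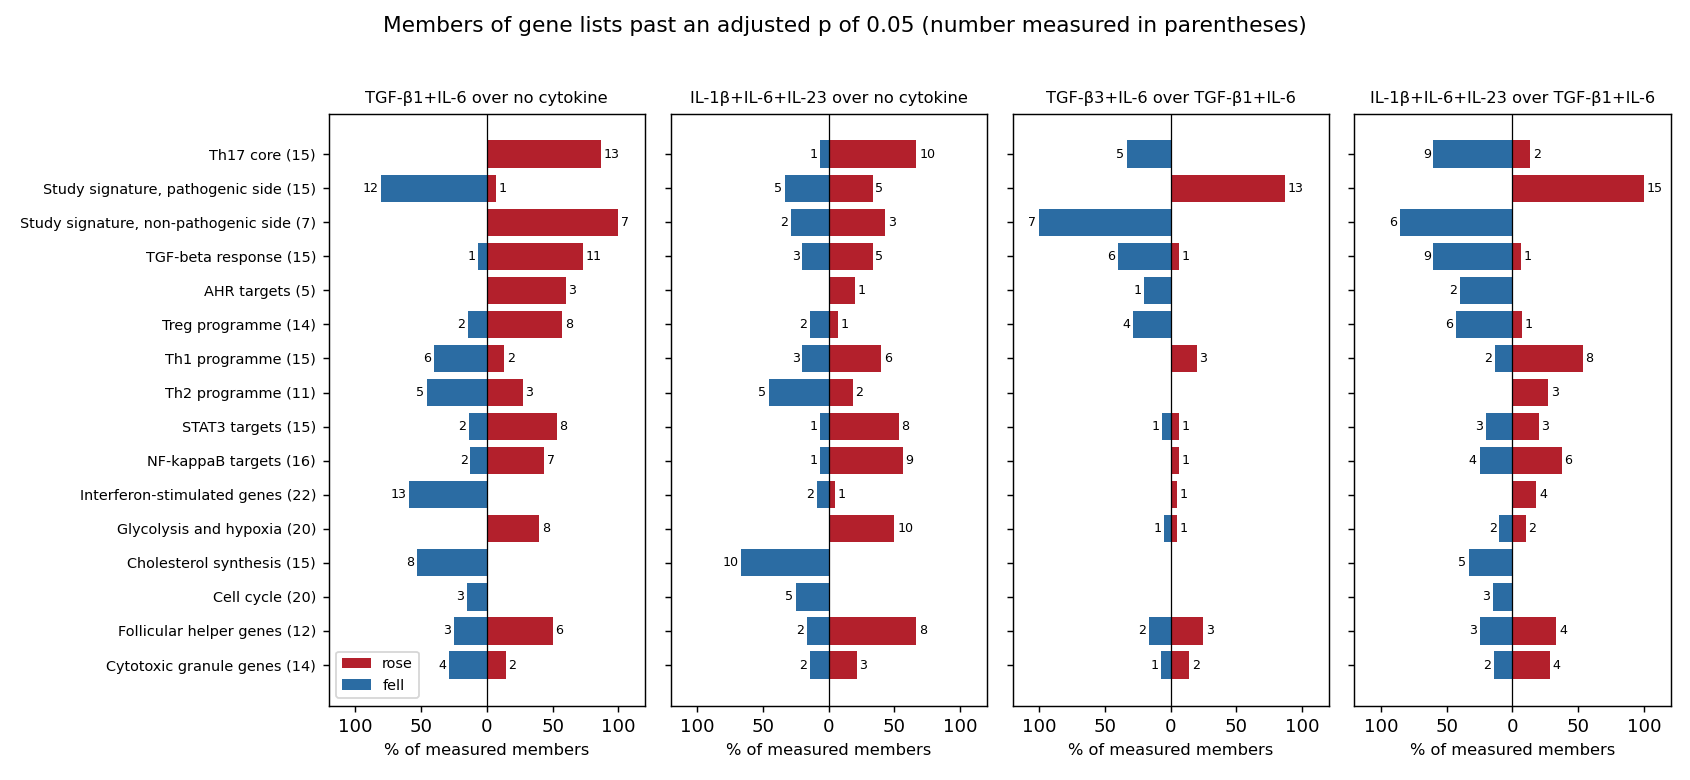
Percent of the measured members of 16 lists called higher (right) or lower (left) in 4 comparisons, one panel each. In IL-1β/IL-6/IL-23 against TGF-β1/IL-6 all 15 genes of the pathogenic side are higher, and in TGF-β1/IL-6 against no cytokine 13 of 15 genes of the Th17 core are higher.

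In total 2379 genes differed between IL-1β/IL-6/IL-23 and TGF-β1/IL-6, 922 higher and 1457 lower, or 1323 and 1405 after a repeated quantile normalisation. Of the 2379 genes, 310 differed at least 2-fold. The count was 3121 within experiment 1, 541 within experiment 2 and 3651 without replicate 1 of IL-1β/IL-6, and 488 of the 489 genes called in both had the same sign. Of the 120 genes that differed by isoform in experiment 2, 115 were also called for IL-1β/IL-6/IL-23 against TGF-β1/IL-6 in experiment 1, on other arrays. All had the same sign, 61 higher against 4.6 for independent lists and 54 lower against 5.6. Fisher's exact test on called genes of either sign, which treats genes as independent, gave p = 1.2e-81. Over all genes, which are not independent, the Pearson r of these log2 differences was 0.63 and the Spearman rho 0.343. For the 823 isoform genes of experiment 1 and the 541 of IL-1β/IL-6/IL-23 in experiment 2, 262 were shared and 260 had the same sign. These overlaps count calls of comparisons that both use TGF-β1/IL-6 as the reference condition, on separate arrays.

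Against TGF-β1/IL-6/IL-23 (n = 2), IL-1β/IL-6/IL-23 (n = 4) had higher Lum by 6.04 ± 0.31, Il3 by 5.27 ± 0.39 and Cxcl3 by 4.25 ± 0.33, and lower Maf by −5.69 ± 0.35 and Il10 by −4.07 ± 0.35. Against TGF-β3/IL-6/IL-23 (n = 2) it had higher Il6 by 3.57 ± 0.26, Lum by 3.19 ± 0.31, Il3 by 2.77 ± 0.39 and Nfkbiz, a target and regulator of NF-κB, by 2.33 ± 0.22, and lower Maf by −4.24 ± 0.35, Pdpn by −3.29 ± 0.17, Ahr by −2.69 ± 0.18 and Il10 by −1.36 ± 0.35. Csf2 was higher by 1.44 ± 0.26 against the TGF-β1 mixture, with an adjusted p of 6.0e-04, while against the TGF-β3 mixture it differed by 0.47 ± 0.26 and did not pass (0.64). Il3 and Cxcl3 with the TGF-β1 mixture and Il6 with the TGF-β3 mixture were near background. Within experiment 1, which held both groups, Il10 measured 43.8 and 35 with IL-1β/IL-6/IL-23 and 176.9 and 141.1 with the TGF-β3 mixture. In experiment 2 it measured 45.2 and 46.4 with IL-1β/IL-6/IL-23. With TGF-β3/IL-6 it measured 159.8 and 161.7 in experiment 1 and 51.3 and 46.7 in experiment 2. The size of −1.36 therefore depends on the experiment term. Against the TGF-β3 mixture 6 of 15 pathogenic side genes were higher and 0 lower (8 and 0 adjusted over the list alone, adjusted p = 0.0071 with an estimated correlation), 6 of 7 non-pathogenic side genes were lower (6 adjusted over the list alone, adjusted p = 0.0071 with an estimated correlation), and 2 of 15 TGF-β response genes were lower (4 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). Genes called numbered 1323 against the TGF-β1 mixture (632 higher and 691 lower) and 372 against the TGF-β3 mixture (211 and 161). Leaving out replicate 1 or 2 of TGF-β1/IL-6/IL-23 gave 797 or 694, and leaving out replicate 1 or 2 of TGF-β3/IL-6/IL-23 gave 134 or 183, while without replicate 1 of IL-1β/IL-6 they numbered 2234 and 815. Il10 against the TGF-β3 mixture did not pass without replicate 1 or 2 of either group (−1.52 to −0.95) or with title numbers as a block (−1.36).

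IL-1β/IL-6 without IL-23 (n = 2) was also set against TGF-β1/IL-6 (n = 4). Gzmb was higher by 5.07 ± 0.33, Serpinb9 by 4.49 ± 0.18, Il3 by 4.21 ± 0.39, Tbx21 by 3.63 ± 0.67 and Ifng by 2.05 ± 0.18. Aqp3 was lower by −5.35 ± 0.17, Nt5e by −4.52 ± 0.23, Il17a by −3.94 ± 0.15 and Maf by −3.49 ± 0.35, while Csf2 differed by −0.02 ± 0.26 and, without replicate 2 of IL-1β/IL-6, was lower by −0.65. Serpinb9 and Ifng with TGF-β1/IL-6 and Nt5e with IL-1β/IL-6 were near background. Of the Th17 core list 11 of 15 were lower and 0 higher (11 and 1 adjusted over the list alone, adjusted p = 0.0034 with an estimated correlation). Of 22 interferon-stimulated genes 14 were higher and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), Ifit1 by 1.87 ± 0.25 for example, and of 20 cell cycle genes 11 were lower and 0 higher (14 and 0 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation). The cell cycle list was called by camera with an adjusted p of 0.00086, which became 0.21 without the array of lower RNA quality, replicate 1 of IL-1β/IL-6. With title numbers as a block, which carries the g difference of the control arrays over, Tbx21 (0.43) and Ifit1 (0.96) did not pass. Genes called numbered 3972, 1025 higher and 2947 lower, or 1804 and 1905 after a repeated quantile normalisation. Without replicate 1 of IL-1β/IL-6 they numbered 1591 (737 and 854), without its replicate 2 they numbered 8882, with title numbers as a block 937, and without replicate 3 of TGF-β1/IL-6 they numbered 2640.

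The 4 arrays without cytokine were compared by title, 2 with an unexplained g against 2 without. Iigp1 was lower in the arrays with g by −3.52 ± 0.17, Tbx21 by −3.20 ± 0.22, Il4 by −2.24 ± 0.14 and the guanylate binding protein Gbp2 by −1.91 ± 0.25. Klrc1, a receptor of natural killer cells, was higher by 1.99 ± 0.30, Igfbp7 by 1.62 ± 0.24 and Lum by 1.38 ± 0.16. The lower levels of Tbx21, Il4 and Klrc1 were near background. Of 22 interferon-stimulated genes 12 were lower and 0 higher (16 and 0 adjusted over the list alone, adjusted p = 0.0018 with an estimated correlation), and of 11 Th2 genes 4 were lower and 0 higher (6 and 0 adjusted over the list alone, adjusted p = 0.0082 with an estimated correlation). By limma 134 genes were called, 57 higher and 77 lower. Leaving out replicate 1, 2, 3 or 4 gave 74, 59, 56 or 56, and leaving out replicate 1 of IL-1β/IL-6 gave 292.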

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

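The tests of explanations and of other splits in this part were chosen only after the result was seen, except the test of the source of the IL-1β/IL-6 cells, and so were the array quality weights and left-out arrays for the isoform effect between experiments.

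Replicate 3 of TGF-β1/IL-6 lay apart from the other 3 arrays of its group in Foxp3 intensity (34.9 against 26.5 to 27.2), with a gap of 0.909 of the range of the group, all of them levels near background. It also lay apart in the difference between the 3′ and 5′ signals of β-actin (0.494 against 0.392 to 0.409), with a gap of 0.833. Chance puts about 1 in 20 groups past the 95% critical value of Dixon's test, and 2 of 52 tests passed it. The effect of IL-23 on IL-1β/IL-6 differed from its effect on TGF-β1/IL-6 at 165 genes and from its effect on TGF-β3/IL-6 at 110 genes by limma. Xist and Eif2s3y were the most extreme of them, so these counts cannot be read as effects of IL-23 alone. The isoform effect differed between experiments at 2 genes by limma, 10 with array quality weights, with 627 at an unadjusted p under 0.05. These were Dsp, the desmosomal protein desmoplakin, at 1.65 ± 0.25, and the PDZ and LIM domain gene Pdlim5 at 1.28 ± 0.18, both with an adjusted p of 0.023 and both named after their values were seen, and Dsp was near background with TGF-β3/IL-6. The count was 0 without any one of replicates 1, 3 and 4 of TGF-β1/IL-6 or replicates 1 to 4 of TGF-β3/IL-6. Transcripts of the Y chromosome, which no comparison of the design used, were present on 12 arrays of cells labelled female.

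Other splits of the same 8 arrays into 4 and 4 were counted for each comparison of groups of 4, and in each 1 of the 35 splits, the real one, called as many genes. Over all splits chance in the grouping could be excluded only if arrays of the 2 experiments could be exchanged for each other. The sex-linked genes speak against this. With TGF-β1/IL-6, Xist measured 49.8 and 57.7 in experiment 1 and 4778.8 and 4402.3 in experiment 2. The splits therefore do not exclude chance. The splits that keep the number of arrays of each experiment in each group number 18 where neither group is that without cytokine and 15 against no cytokine, which is too few for a share under 0.05. Each other split mixes arrays of both groups, which widens the spread, so its low count does not measure how many genes would be called between groups with no difference. Without an exchange of arrays, the isoform comparison called 101 genes in both experiments, on separate arrays, all with the same sign (48 higher against 1.2 for independent lists, 53 lower against 1.5), and 488 of 489 shared calls of IL-1β/IL-6/IL-23 against TGF-β1/IL-6 had the same sign, which argues against chance in these 2. Against no cytokine, Il17a measured 69.9 or lower on each control array and 6699.7 or higher on each array of the 3 mixtures. TGF-β3/IL-6 against TGF-β1/IL-6 had 569 genes and at most 1 in the other splits, and IL-1β/IL-6/IL-23 against TGF-β1/IL-6 had 2379 and at most 0 by limma. Against no cytokine, IL-1β/IL-6/IL-23 had 2485 genes and at most 15, TGF-β1/IL-6 had 3590 and at most 2, and TGF-β3/IL-6 had 2918 and at most 2. At an unadjusted p under 0.05 the other splits reached 1439, 2195, 2251, 2159 and 1939 genes in that order.

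Most genes called between IL-1β/IL-6/IL-23 and IL-1β/IL-6 were lower without IL-23, 720 of 951. The tables argue against taking this lean as an effect of IL-23 alone, since 116 genes were called without the low-quality array, replicate 1 of IL-1β/IL-6, 63 of them higher with IL-23 and 53 lower, and 8428 without its replicate 2. Low quality of that array is a candidate explanation of the lean, although leaving it out also left 1 array to stand for the group. The source of the cells stays open, since the correlation of the difference with that between experiments was 0.19 over 112 called genes that are not sex-linked, between the bounds of 0.1 and 0.3 set for it. The effect of IL-23 itself, which the design names, stays open and was not tested for this lean, as does the sex of the mice, and in a block on title numbers, whose 1 and 2 in experiment 2 belong only to the IL-1β/IL-6 arrays and to the control arrays without g, 101 genes were called, 65 of them higher with IL-23.

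Y-linked transcripts were present on arrays of cells that the labels call female. Male RNA mixed into that of female cells is argued against, because the highest Xist among these arrays was 1.94% of the median of the others. An exchange of the IL-1β/IL-6 arrays with arrays of experiment 1 is argued against as well, since 0 arrays of experiment 1 lacked the Y-linked transcripts. All 12 arrays had the 3 Y-linked transcripts and little Xist, which is consistent with cells from male mice, as a hypothesis. What a difference in sex, if there was one, does to the comparisons with IL-1β/IL-6, whose 2 arrays were those of experiment 2 with Y-linked transcripts, was not tested apart from the source of the cells.

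Interferon-stimulated and Th2 genes were lower on the 2 arrays without cytokine whose titles have a g. RNA quality is argued against, because replicate 1, whose β-actin difference lay between those of the arrays with g, had interferon-stimulated genes higher than them by a median of 0.73 on the log2 scale (0.78 for replicate 2). Other cell types as a source of the transcripts stay open, although the cells were sorted as CD4, CD44-low and CD62L-high before culture and 0 of 43 markers of other types passed the threshold by limma (1 lower and 1 higher at an unadjusted p under 0.05), since most of these markers lay near the background and 0 cell types could be excluded, the 4 brighter myeloid and dendritic markers having a median log2 difference of −0.12 with an SD of 0.35. A batch that follows the title numbers cannot be told apart from the g, since the arrays without g are numbers 1 and 2, and the IL-1β/IL-6 arrays of these numbers resembled them in Iigp1. What the g stands for is unexplained in the labels, and no biological explanation was tested.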

How the results depend on the processing

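The alternatives that left replicate 1 of IL-1β/IL-6 out of the whole fit, placed the IL-1β/IL-6 arrays with experiment 1 or used only the control arrays with g were chosen after seeing the data, as were all alternatives for the interactions of IL-23, for the difference of the isoform effect between experiments and for the control arrays with and without g. The array signal over background and the number of arrays limit what can be called, so genes near the background are understated. When single arrays were left out, genes called against no cytokine ran from 1419 to 9012 for IL-1β/IL-6, 1956 to 2275 for IL-1β/IL-6/IL-23, 2970 to 3321 for TGF-β1/IL-6, 1422 to 2268 for TGF-β1/IL-6/IL-23, 2101 to 2643 for TGF-β3/IL-6 and 981 to 1699 for TGF-β3/IL-6/IL-23. The isoform comparison ran from 366 to 522 without IL-23 and 64 to 103 with it. Adding IL-23 to IL-1β/IL-6 ran from 116 to 8428, and adding it to either TGF-β mixture stayed at 0 by limma, with 661 and 380 at an unadjusted p under 0.05 on all arrays. IL-1β/IL-6 against TGF-β1/IL-6 ran from 1591 to 8882, and IL-1β/IL-6/IL-23 ran from 1798 to 2184 against TGF-β1/IL-6, 694 to 1259 against TGF-β1/IL-6/IL-23 and 134 to 351 against TGF-β3/IL-6/IL-23. The interactions of IL-23 ran from 47 to 7295 and 41 to 6596, the difference of the isoform effect between experiments from 0 to 2, and the control arrays by title from 56 to 74. A group left with 1 array was assumed to vary like the others. In the 3 direct comparisons with IL-1β/IL-6 the lowest count came without its replicate 1 and the highest without its replicate 2, as did the highest of both interactions, and the other extremes came without other arrays.

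Counts moved by over 1.5 times under these settings, and where no reason is given the cause was not tested. Experiment 2 alone called 1964, 920, 2115 and 1487 genes against no cytokine for IL-1β/IL-6, IL-1β/IL-6/IL-23, TGF-β1/IL-6 and TGF-β3/IL-6, then 120 for the isoforms, 71 for IL-23 added to IL-1β/IL-6, and 1270 and 541 for IL-1β/IL-6 and IL-1β/IL-6/IL-23 against TGF-β1/IL-6. Experiment 1 alone called 462 for the isoforms with IL-23, and 2260 and 810 for IL-1β/IL-6/IL-23 against them. Without the experiment term the counts were 3026 for IL-1β/IL-6 and 2894 for TGF-β3/IL-6/IL-23 against no cytokine, 340 and 95 for the isoforms without and with IL-23, 40 and 41 for the interactions, 1 between experiments and 64 by title. A fit to only the groups compared gave 454, 5921 and 5157 against no cytokine for IL-1β/IL-6 and the TGF-β1 and TGF-β3 mixtures with IL-23, 1071 for the isoforms, 36 for IL-23 added to IL-1β/IL-6 and 597 for IL-1β/IL-6 against TGF-β1/IL-6. This fit had no experiment term where a group was missing from an experiment, which among these holds for all but the isoforms. The 5921 and 5157 compare arrays of experiment 1 with controls of experiment 2, so cytokines and experiment cannot be told apart there. Without the control arrays with g, 1944, 1505 and 1905 genes were called for IL-1β/IL-6, IL-1β/IL-6/IL-23 and TGF-β3/IL-6. An absolute log2 difference of 1, stricter by construction, gave 354, 303, 552, 584, 358 and 408 against no cytokine in the order IL-1β/IL-6, with IL-23, TGF-β1/IL-6, with IL-23, TGF-β3/IL-6, with IL-23. It gave 78 and 78 for the isoforms, 123 for IL-23 added to IL-1β/IL-6, 461 for IL-1β/IL-6 against TGF-β1/IL-6, and 310, 323 and 113 for IL-1β/IL-6/IL-23 against TGF-β1/IL-6 and the TGF-β1 and TGF-β3 mixtures with IL-23.

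Array quality weights gave both IL-1β/IL-6 arrays a weight of 0.11, which by construction cannot part the 2 arrays of a group, and called 150 genes for IL-1β/IL-6, 4321 for IL-1β/IL-6/IL-23, 4465 for TGF-β1/IL-6/IL-23, 4384 for TGF-β3/IL-6 and 3227 for TGF-β3/IL-6/IL-23 against no cytokine. They called 1525 and 468 for the isoforms, 9 for IL-23 added to IL-1β/IL-6 and 4 added to TGF-β1/IL-6, 252 for IL-1β/IL-6 and 3763 for IL-1β/IL-6/IL-23 against TGF-β1/IL-6, 2582 and 666 against the mixtures with IL-23, 9 and 8 for the interactions, 10 between experiments and 389 by title. Leaving replicate 1 of IL-1β/IL-6 out of the whole fit gave 3967, 3725 and 3160 against no cytokine for IL-1β/IL-6/IL-23 and the TGF-β1 and TGF-β3 mixtures with IL-23, 1110 and 333 for the isoforms, 3651, 2234 and 815 for IL-1β/IL-6/IL-23 against the TGF-β mixtures, 8 between experiments and 292 by title. With it left out, camera called the cell cycle list (adjusted p of 0.0082) and the integrated stress response list (0.023) lower with IL-23 added to IL-1β/IL-6, where the direction with it was upward and not called. The IL-1β/IL-6 arrays placed with experiment 1 gave 5047 for IL-23 added, 6271 against TGF-β1/IL-6, and 1338 and 1041 interactions. This turned the sex-linked genes, by construction, to −0.06 for Eif2s3y and 0.44 for Xist against no cytokine, 0.02 and −0.67 with IL-23 added, and 0.67 for Xist against TGF-β1/IL-6. Only the control arrays with g turned Tbx21 to 0.63, 1.39 and 1.40 for TGF-β1/IL-6, TGF-β3/IL-6 and TGF-β3/IL-6/IL-23. With fry, which compares with no other genes, the effector cytokine list took the other direction against no cytokine for IL-1β/IL-6/IL-23, TGF-β1/IL-6 and TGF-β3/IL-6 (adjusted p 0.0044, 0.042 and 0.006), and the co-inhibitory receptors against TGF-β1/IL-6 for IL-1β/IL-6 and IL-1β/IL-6/IL-23 (0.00083 and 0.026).

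Across all samples the culture numbers gave no clear pairing, and pairing by title number could not be judged. Of 54 pairs with the same title number 17 had deviations correlated above 0.1 (−0.17 to 0.6), and 12 of 22 arrays correlated best with their own number. The experiment was not removed from these deviations, and it goes with the title number in groups of both experiments. The check of title numbers therefore cannot tell pairing from experiment. Of 20 pairs with the same culture number 5 were correlated above 0.1 (−0.229 to 0.261). In experiment 2, though, the IL-1β/IL-6 arrays and the control arrays without g shared the lower title numbers and a high Iigp1. The block on title numbers gave 2381 genes for IL-1β/IL-6 against no cytokine, 101 for IL-23 added to it and 937 for it against TGF-β1/IL-6. Its step from numbers 1 and 2 to the higher ones rests only on the control arrays with and without g, so it carries their difference over. The block turned Tbx21 to 0.63, 1.39 and 1.40 for TGF-β1/IL-6, TGF-β3/IL-6 and TGF-β3/IL-6/IL-23 against no cytokine, the values found with only the control arrays with g. With IL-23 added to IL-1β/IL-6 it turned Iigp1 to 0.02, Gbp6 to 0.07 and Tbx21 to 1.86. With this block 18 of 351 called gene results no longer passed and 2 turned. The block on culture numbers moved none of the 15 counts, and 3 of 351 no longer passed.

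None of 15 total counts moved after centring each array, a repeated quantile normalisation, a trend with robust variances, the experiment as a random block (correlation 0.233), a filter on dim genes, the mean of probe sets or leaving out less specific probe sets. Under these settings 349, 350, 350, 349, 345, 348 and 349 called gene results kept their direction and side of the threshold, of 351, 351, 351, 351, 345, 351 and 349. The remainder, at most 3 per setting, no longer passed and had the same direction. The repeated quantile normalisation did change the balance of higher and lower genes within a total. Higher genes went from 220 to 349 for the isoforms without IL-23, and for IL-1β/IL-6 from 1025 to 1804 against TGF-β1/IL-6 and from 1386 to 2248 against no cytokine. Lower genes went from 231 to 434 with IL-23 added to IL-1β/IL-6. Calls were lost, in the same direction, by 31 of 368 gene results with array quality weights, 28 of 231 in experiment 2 alone, 19 of 368 without the experiment term and 16 of 351 with only the groups compared. They were lost by 6 of 359 with the IL-1β/IL-6 arrays placed with experiment 1, 3 of 167 without the control arrays with g, 4 of 167 with only those, 1 of 132 in experiment 1 alone and none of 284 without replicate 1 of IL-1β/IL-6. Of 140 called list results, 44 stayed called with an estimated correlation, 112 with fry, 126 without the experiment term and 128 without replicate 1 of IL-1β/IL-6, and 96, 28, 14 and 12 were lost.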

Other observations

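The lists, the tests and the rule for naming genes were fixed in advance, while Serpinb9, Serpinb6b and Mt2 were picked by that rule for the size of their change. The lists described here, and the comparison of Serpinb9 and Serpinb6b with Gzmb, were chosen after their values were seen. Serpinb9 and Serpinb6b, protease inhibitors of which Serpinb9 blocks granzyme B, moved in the same direction as Gzmb in the comparisons given next. Whether they follow Gzmb in every comparison is not claimed. Relative to no cytokine, TGF-β1/IL-6 changed Serpinb9 by −5.38 ± 0.15 (25.4 ± 3.48 against 1284 ± 191, n = 4 each) and Serpinb6b by −4.73 ± 0.18, beside −5.96 ± 0.27 for Gzmb. The level of Serpinb9 with TGF-β1/IL-6 was near background, so the sizes of its differences from it are not exact. With TGF-β3 in place of TGF-β1, Serpinb9 was higher by 1.51 ± 0.14 and Serpinb6b by 2.04 ± 0.16, and Gzmb by 2.26 ± 0.25. Mt2, a metallothionein that binds zinc, rose in all 6 mixtures, by 4.88 ± 0.13 with TGF-β1/IL-6 (5629 ± 1310 against 213.8 ± 48.9), 4.90 ± 0.13 with TGF-β3/IL-6, 4.64 ± 0.13 with IL-1β/IL-6/IL-23 and 4.29 ± 0.15 with IL-1β/IL-6. Limma adjusted p was 5.1e-07 or lower for each of these differences of Serpinb9, Serpinb6b and Mt2.

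With IL-1β/IL-6/IL-23, 8 of 12 follicular helper genes rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.013 with an estimated correlation). The B cell coactivator gene Pou2af1 rose by 1.54 ± 0.23, Bcl6, the regulator of follicular helper cells, by 1.37 ± 0.14 and the chemokine receptor Cxcr5 by 0.86 ± 0.21, while the receptor Slamf6 changed by −1.25 ± 0.15. Of 15 genes of cholesterol synthesis 10 fell and 0 rose (12 and 0 adjusted over the list alone), with an adjusted p of 6.1e-12 by camera that became an adjusted p = 0.12 with an estimated correlation. Dhcr7 changed by −0.98 ± 0.15 and Idi1 by −0.80 ± 0.10. Of 20 genes of glycolysis and hypoxia 10 rose and 0 fell (14 and 0 adjusted over the list alone), with an adjusted p of 9.1e-09 that became an adjusted p = 0.25 with an estimated correlation, Egln3, an oxygen sensor, by 1.50 ± 0.11 and the glucose transporter Slc2a3 by 0.95 ± 0.22 among them. With TGF-β1/IL-6, 12 of 15 genes of the pathogenic side fell against no cytokine and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.0085 with an estimated correlation), and all 7 of the non-pathogenic side rose (7 adjusted over the list alone, adjusted p = 0.0084 with an estimated correlation), for lists the study chose on these samples.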
